A study of Mus musculus with 47 samples.

How the data were processed

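RNA-seq gene expression was measured in 47 libraries of mouse T-cell precursors. Per the labels' protocols, total RNA was extracted with Trizol, selected in repeated rounds on oligo-dT beads, fragmented, converted to cDNA by random priming and built into libraries, with no step listed that marks strand. Reads from a gene and from an overlapping antisense gene therefore cannot be told apart. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to the mapped fragments), which its name describes as merged and adjusted with ComBat, a method that removes batch differences. The reads were aligned to mouse build mm9, per the submitters' processing notes. The aligner, the quantification tool, and the batches and covariates given to ComBat are not given in the sources used here. No coordinates are printed.

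The table held 17754 genes, each with a symbol and an Ensembl identifier, and 92 symbols named 2 entries each. Library columns were matched to samples through the number in each sample's description. A further 16 columns of per-sample values matched no sample and were not used. The lowest value in the table was 0.1 FPKM, which acted as a floor, and between 0.47% and 6.67% of genes per library stood at it. A value of 0.1 is therefore read as not detected, and fold changes against it are not bounds. Column totals ran from 581205 to 1005744 FPKM. Sequencing depth is unknown from these values, so no counting interval is given. Gene classes and current symbols were looked up by Ensembl identifier in GENCODE M21, where 16481 identifiers had an entry; the symbol Spi1 stands for an entry that carries an older symbol. Because the adjustment used group or batch information that is not known here, it could have moved the differences reported in either direction.

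Groups were taken from the titles and characteristics. All analyses used log2(FPKM + 1), so differences of genes with low values are understated. A gene was tested when it reached 1 FPKM in at least as many fitted libraries as the smaller group held. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a mean-variance trend in the empirical Bayes step and Benjamini-Hochberg adjustment. Genes with an adjusted p under 0.05 are called. The fetal liver knockout comparison had stroma and IL-7 as covariates, and the GSI comparison had the stage. Interaction terms tested knockout by stroma, knockout by culture day and GSI by stage. There were 6 fitted comparisons and 6 comparisons of single libraries, which carry no test. For the latter, the median difference of a gene list was placed among 10000 random lists of equal size, matched on mean expression in 20 bins, as a description of those libraries only. Fold changes of separate comparisons were set side by side with correlations across genes, which are not independent replicates, and with Fisher's exact test for overlaps. None of those pairs of comparisons shared a library.

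The main designs, the alternatives and 14 gene lists were written before the data were examined, as was the rule for the genes named. That rule took 19 fixed genes, the 8 called genes with the most positive and the 8 with the most negative difference among those with a group mean of at least 5 FPKM, and up to 4 called members of each list, or its 2 most abundant members where none was called. Predicted genes, pseudogenes, small RNAs and receptor segments were left out of the middle part. For single libraries it took the fixed genes and the 5 largest differences each way. Members not in the table included Tbx21 and Il1rl1 of the innate lymphoid list, Pax5, Vpreb3, Blnk and Ms4a1 of the B-cell list, Cd14 of the myeloid list, Il17a, Il17f and Il23r of the type 17 list, Il1rl1 and Il23r of the receptors, Lum of the stromal list and Atf3 of the immediate early list. Lists were tested with camera in limma, using an inter-gene correlation estimated from the data; a preset correlation of 0.01 was the alternative. Other alternatives were a pseudocount of 0.1, no filter, quantile normalization, robust variances, each library left out, other covariates and subsets, and replicate blocks.

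Knockout and control libraries shared title date, stroma and IL-7 in 9 pairs, 3 of which are the same cultures on different days, and treated and untreated GSI libraries shared title dates in 4 pairs, so that the pairing comes from the labels. DN2a and DN2b replicates 1 shared a title month and replicates 2 a title date, which the fitted stage comparison did not include. Deviations from the means of the groups (stage and GSI, or genotype and stroma) correlated between 0.648 and 0.713 within the GSI pairs and between -0.118 and 0.524 within the knockout pairs. With 2 GSI libraries per stage, the 4 GSI pairs give only 2 separate correlations. No columns were identical, and the highest correlation of any pair of libraries was 0.986. Some libraries came from 1 culture harvested on several days, and for the rest the labels do not always say whether cultures were separate. The p-values then measure only the spread between these libraries, part of which may be technical.

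The fitting script was tested on simulated log2 values with the fitted means and residual spread of each comparison and 200 changed genes. With differences of 1 on the log2 scale, 93% were recovered in the knockout comparison (12678 genes), 57% in the GSI comparison (12783 genes), 40% in the stroma interaction (14271 genes), 20% in the DN2a against DN2b comparison (13364 genes) and 7% in the culture day interaction (13674 genes). With differences of 2, the shares were 100%, 91%, 84%, 80% and 59%. The GSI by stage interaction (13873 genes) recovered 0% at either size.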

Results

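The transcriptomes of 47 libraries of mouse T-cell precursors were compared, 19 of them labelled as Bcl11b knockout and 4 treated with a gamma-secretase inhibitor (GSI), which blocks Notch signalling. Bcl11b encodes a zinc-finger transcription factor that is switched on as precursors commit to the T lineage. The cells were staged as DN2a, DN2b and DN3, successive double-negative stages. Most came from fetal liver precursors grown on OP9-DL1 or OP9-DL4 stroma, which present the Notch ligands Delta-like 1 and 4. The main comparison held 14 fetal liver knockout libraries (8 on DL1, 6 on DL4) and 11 controls (8 on DL1, 3 on DL4), all from cells given a Cre retrovirus. Titles of the controls name B6 cells, and knockout titles do not, so the mouse line may differ together with the genotype. Control titles name Cre in the later years but not in the earliest. The protocol gives a DN2a sort phenotype for floxed cells and DN2b for controls, while the stage label of all 14 knockout libraries is DN2. Titles name DN2a for 8 knockout libraries, DN2 for 5 (DL1 replicates 3, 4, 5, 6 and 8) and DN2b for 1 (DL1 replicate 7), and DN2b for 8 controls and DN2 for 3. Untreated cells without Cre gave 4 DN2a and 2 DN2b libraries, and GSI gave 2 of each stage. DN2b replicate 1, untreated and with GSI, is titled DN3 but staged DN2b. The remaining libraries were from bone marrow, thymus and vector-transduced cells, mostly 1 per condition. Libraries had between 11756 and 13370 genes at 1 FPKM or more.

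Bcl11b itself was measured in every library. In the fetal liver cultures it averaged 23.96 ± 7.06 FPKM (SD, n = 14) in knockout and 56.4 ± 19.8 FPKM (SD, n = 11) in control, a log2 difference of -1.22 (SE 0.21, limma adjusted p = 0.000127), lower in 8 of 9 date-matched pairs. Of these pairs, 3 are 1 control and 1 knockout culture sampled on days 9, 10 and 12, so that the 9 hold 7 pairs of cultures. Knockout libraries ranged from 8.8 to 37.9 FPKM and controls from 16.9 to 84.4 FPKM. The lowest, the library labelled control DL1 replicate 1, lay inside the knockout range, while its Cd3e (145.5 FPKM) and Zbtb16 (at the floor) lay on the control side. Without it 2246 genes were called in the comparison below. Transcript remained in every knockout library, and the labels do not say which part of the gene was removed, so that a gene-wide FPKM checks the label only in part. Among libraries without replicates, Bcl11b stood at 36.4 FPKM in the LckCre thymic knockout against 105.4 in its control, and at 23.8 in the cultured thymic DN3 knockout against 61.2 and 79.3 in the cultured controls. It was 24.7 FPKM in the knockout with empty vector, 105.4 with the Bcl11b vector and 41.4 in the control with empty vector. In bone marrow the library labelled knockout had 45.0 FPKM and its control 44.9 FPKM, so Bcl11b did not separate these libraries. Untreated DN2a cells, which had no Cre, held 8.69 ± 6.88 FPKM (SD, n = 4), below the knockout mean.

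**Figure D1:**
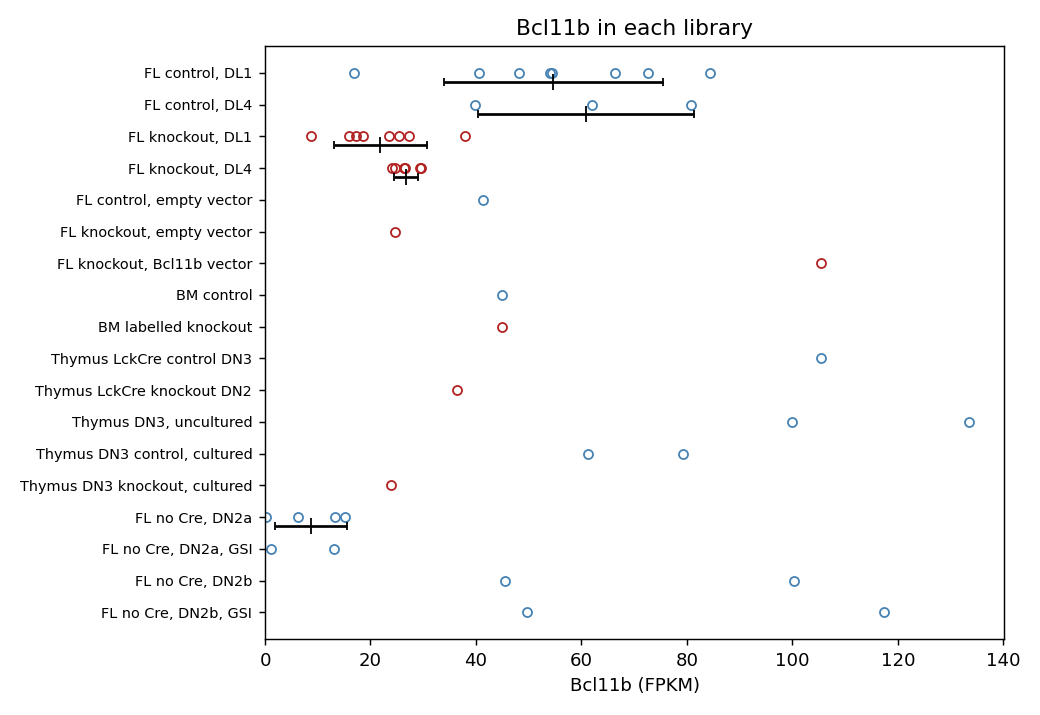
Bcl11b level in FPKM (x axis) for each library, with 1 row per group and 1 circle per library (red, labelled knockout; blue, others); black marks show the mean and SD of groups with more than 2 libraries. Fetal liver knockout libraries lie between 8.8 and 37.9 FPKM, and the bone marrow library labelled knockout lies at the level of its control.

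In fetal liver cultures labelled knockout, 11 of 19 T-cell receptor genes were lower, and 12 of 18 innate lymphoid and 10 of 14 progenitor genes were higher. None of these 3 lists passed as a set with an estimated correlation and without date pairs as a block (adjusted p = 0.0574, 0.0741 and 0.0574). Cd3e, which encodes a signalling chain of the T-cell receptor complex, fell from 107 ± 46.2 FPKM (SD, n = 11) to 15.6 ± 17.8 FPKM (SD, n = 14), a log2 difference of -3.84 (SE 0.51, limma adjusted p = 3.85e-06). Zbtb16, which encodes the innate-like lymphocyte regulator PLZF, rose from 9.89 ± 6.92 to 45.7 ± 24.8 FPKM, a log2 difference of 2.26 (SE 0.43, adjusted p = 0.000354), higher in 8 of 9 pairs. Id2, an inhibitor of E proteins needed by innate lymphoid and NK cells, rose from 32.5 ± 12.6 to 73.4 ± 25.8 FPKM and was higher in 9 of 9 date-matched pairs. The differences of Zbtb16, Id2 and Kit were larger in cultures with reduced IL-7, nearly all of them from the earliest year of the titles. Of 12678 genes tested, 2142 were called, 1242 higher and 900 lower in knockout, and 241 and 136 of these differed by 2-fold or more.

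Of 18 innate lymphoid and NK genes tested, 12 were higher in knockout and 0 lower; adjusted over the list alone, 16 were higher and 1 lower. Tyrobp (log2 difference 3.43) and Fcer1g (2.72), adaptors of activating receptors, were higher in 9 of 9 pairs, and so was the NK receptor gene Klrd1 (2.09). Il2rb, the IL-2 and IL-15 receptor beta chain, rose by 1.69 and Nfil3, a regulator of NK and innate lymphoid development, by 1.16. The list did not pass as a set with the estimated correlation (adjusted p = 0.0741), while a preset correlation gave adjusted p = 3.61e-09.

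Of 19 T-cell receptor signalling and T-lineage genes tested, 11 were lower and 0 higher; adjusted over the list alone, 12 were lower. Cd3d (-2.92), Cd3g (-2.47) and Ptcra (-2.22), the pre-T-cell receptor alpha chain, were lower in 9 of 9 pairs. The recombinase gene Rag1 (-0.55, SE 0.38) was not called. As a set the list had adjusted p = 0.0574 with an estimated correlation, and adjusted p = 0.0424 in the fit with date pairs as a block. With the 3 pairs of the same cultures averaged, the blocked value was 0.0798, and no list passed. With the preset correlation its adjusted p was 1.71e-09.

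Progenitor regulators, transcription factors and receptors of uncommitted cells, were higher for 10 of 14 members and lower for 0; adjusted over the list alone, 11 were higher. Gfi1b (1.48), Bcl11a (1.42), Hhex (1.28) and Spi1 (0.97), which encodes PU.1, led the list. Kit rose by 0.96, although Kit was also a sorting marker and its level separates the DN2a from the DN2b gate. The set had adjusted p = 0.0574 with an estimated correlation and 3.5e-08 with the preset one.

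T-lineage transcription factors split. Of 17 tested, 2 were higher and 3 lower; adjusted over the list alone, 3 were higher and 5 lower. Id3 (-1.99), Spib (-1.63) and Ets1 (-0.92) fell, Ikzf2 (0.82) and Gata3 (0.78) rose, and Tcf7, an early T-cell factor, differed by -0.13 (SE 0.16) and was not called. Notch target genes split as well, with 3 of 12 higher and 2 lower, and 3 and 3 when adjusted over the list alone. Nrarp, a feedback inhibitor of Notch, rose by 1.94 in 9 of 9 pairs, while Ptcra and Notch3 (-0.95) fell and Hes1 (-0.10) and Dtx1 (-0.85) were not called. Cytokine receptors were higher for 6 of 13 members and lower for 2 (7 and 2 adjusted over the list alone), including Il18rap (1.07) higher and Il21r (-1.05) lower. With an estimated correlation the adjusted p was 0.702 for the transcription factors, 0.997 for the Notch targets and 0.636 for the cytokine receptors.

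**Figure D2:**
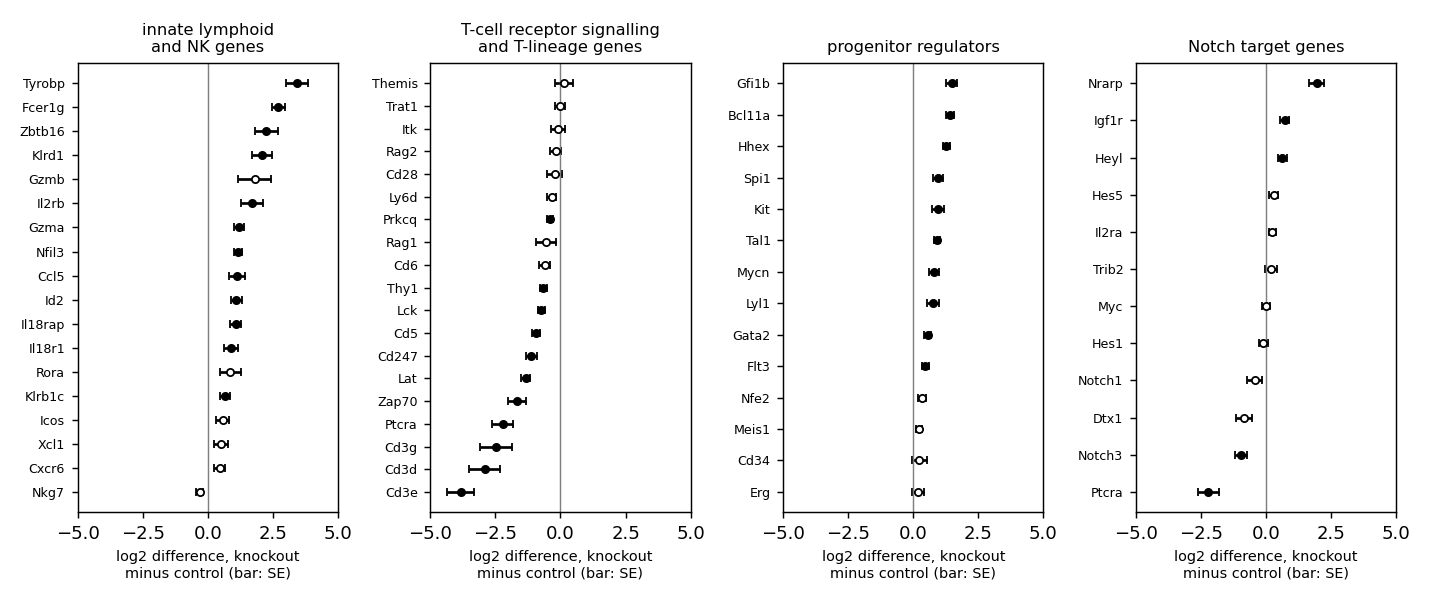
Log2 difference, knockout minus control (x axis; bars, SE), for each tested member of 4 gene lists in fetal liver cultures (n = 14 and 11); filled circles were called. In the innate lymphoid list 12 of 18 members lie to the right of 0 and are filled, and in the T-cell receptor list 11 of 19 lie to the left and are filled.

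Lists for other cell types and states were tested in the same way. Myeloid and dendritic genes had 3 of 11 higher and 0 lower, among them Fcgr3 (3.97), an Fc receptor gene that NK cells also express, and Cebpb (0.90). B-cell genes had 2 of 5 higher, Pou2af1 (1.14) and Btk (1.09), and 2 lower, Vpreb1 (-0.71) and Cd79b (-0.46). Gamma-delta and type 17 genes had 1 of 4 higher, Maf (0.85), and 1 lower, Sox13 (-1.71). Beta-selection and double-positive genes had 1 of 10 lower, Slamf1 (-0.59). Erythroid markers had 1 of 4 higher, the globin gene Hbb-b2 (1.34), whose reads can be shared with near-identical globin genes. The immediate early and heat-shock list had 1 of 8 lower, Dnajb1 (-0.36), and 0 of 16 proliferation genes and 0 of 9 stromal markers were called. Adjusted over the list alone, each of these 8 lists gave the same counts. With an estimated correlation the adjusted p was 0.563 for the myeloid, gamma-delta and immediate early lists, 0.702 for the double-positive list and 0.997 for the B-cell, erythroid, proliferation and stromal lists.

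Genes outside the lists with the most positive differences were Tnni1 (4.89), Itga2b (3.73), Dlk1 (3.57), Fgf3 (3.52), Trf (3.26) and Trpm1 (3.16). Those with the most negative were Gbp6 (-3.38), Crip1 (-2.79), Myl10 (-2.72), Ccdc153 (-2.65) and Tubb2b (-2.49). Each of these differed in the stated direction in 9 of 9 pairs. Itga2b, Fgf3, Trf, Gbp6 and Tubb2b were also among the largest differences between untreated DN2a and DN2b cells, in the same direction (below). The block, on 9 pairs, called 1282 genes, 659 higher and 623 lower. Of the called genes named above, 6 were not called with it: Kit (adjusted p = 0.0576), Ikzf2 (0.0778), Maf (0.199), Cd79b (0.162), Dnajb1 (0.0556) and Crip1 (0.149). Kit and Ikzf2 were higher in 8 of 9 pairs and Maf in 6. The gamma-delta list then had 0 members higher and 2 lower, and the double-positive list 2 of 10 lower, or 6 adjusted over the list alone (as a set, adjusted p = 0.088). Erythroid markers had 1 higher and 1 lower adjusted over the list alone. With the 7 pairs of cultures as blocks, 858 genes were called. The same 6 genes were not among them, nor were Il2rb (adjusted p = 0.0553), Il18rap (0.0589), Id3 (0.0681), Ets1 (0.0702), Cebpb (0.142), Hbb-b2 (0.154) and Notch3 (0.181). With those 7 pairs, 7 innate lymphoid and 6 progenitor genes were higher and 10 T-cell receptor genes lower. Quantile normalization called 1132 genes higher and 1218 lower, so the balance of higher against lower calls depended on scaling. With the 3 pairs whose controls were also titled DN2, 131 genes were called; these are the 3 pairs of the same cultures and are not independent replicates. Titles carry dates of 3 years; within the earliest, the middle and the latest year, 475, 270 and 778 genes were called.

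The knockout difference was compared between stromas and between culture days. No gene was called for the knockout by stroma interaction among 14271 tested with limma, where 338 had an unadjusted p under 0.05. Among libraries with standard IL-7, all on DL1 were titled with the latest year and all on DL4 with the middle year. Stroma and year cannot be told apart in those libraries, which limits the DL1 and DL4 values below. Cd3e differed by -4.23 (SE 0.58) on DL1 and by -2.59 (SE 0.60) on DL4, and Ptcra by -2.71 (SE 0.53) and -1.21 (SE 0.36). The interaction of Cd3e was 1.58 (SE 1.07) and was not called. Zbtb16 differed by 2.08 (SE 0.52) on DL1 and 2.40 (SE 0.60) on DL4. Between days 9 to 10 and day 12 on DL1, 0 of 13674 genes were called and 312 had an unadjusted p under 0.05. Zbtb16 differed by 0.76 (SE 0.39) on the earlier days and by 1.91 (SE 0.37) on day 12. Id2 differed by 0.38 (SE 0.27) and 1.17 (SE 0.30), and neither interaction was called. The fit ignored that knockout replicates 3 to 5, knockout replicates 6 and 7, and control replicates 4 to 6 are each 1 culture over time. Zbtb16 was 8.5, 23.9 and 25 FPKM in the first culture, 17.5 and 78 in the second and 10.8, 9.7 and 8.8 in the control. Id2 was 38.2, 57.8 and 48.4 FPKM, then 31.6 and 87.2, and 32.3, 43.7 and 24 in the control. Nrarp was higher at both times, by 1.99 (SE 0.30) and 2.47 (SE 0.34). Leaving out 1 library gave 4 calls for stroma without knockout DL1 replicate 1 and 1 without control DL4 replicate 1 or knockout DL4 replicate 2. It gave 2 calls for day without control DL1 replicate 6, and 0 without any other library.

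GSI was given to normal precursors at 1 µM for the last 12 h, so that loss of Bcl11b could be set beside loss of Notch signalling. Among Notch target genes, Dtx1 and Nrarp were lower after GSI when adjusted over that list. Dtx1, a direct Notch target, was 12.7 ± 2.31 FPKM (SD, n = 4) with GSI and 48.9 ± 27.3 FPKM (SD, n = 4) without, a log2 difference of -1.70 (SE 0.27) and lower in 4 of 4 pairs. Nrarp differed by -0.53 (SE 0.13) and Hes1 by -0.39 (SE 0.15), each lower in 4 of 4 pairs. Adjusted over the list alone, 2 of 12 Notch target genes were lower, Dtx1 (limma adjusted p = 0.00253) and Nrarp (limma adjusted p = 0.0163), and 3 were lower with pairs as a block. Over all 12783 genes tested with limma, 0 were called and 297 had an unadjusted p under 0.05. With pairs as a block limma called 0 and gave 1323 such genes. Without any difference a share of about 0.05 would be expected, more than the first count and less than the second. The first fit ignored the pairs, whose deviations correlated between 0.648 and 0.713.

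The Notch list as a whole had a median difference of -0.38. Its adjusted p was 0.175 with an estimated correlation and 4.89e-07 with the preset one. In each other list 0 members were called with limma, and 0 were called adjusted over the list alone; each had adjusted p = 0.724 with an estimated correlation. With pairs as a block and adjusted over the list alone, innate lymphoid, T-lineage factor and cytokine receptor genes each had 1 higher and 1 lower. T-cell receptor and progenitor genes each had 1 lower. Innate lymphoid genes had a median difference of 0.13 and T-cell receptor genes one of 0.06. Stromal markers, which would come from the feeder cells, had a median of 0.26 and passed with the preset correlation alone (adjusted p = 0.00868). GSI by stage interaction was called for 0 of 13873 genes (129 with an unadjusted p under 0.05), in a design that recovered no simulated change. The pair of DN2b replicate 1, titled DN3, was part of every GSI fit.

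Knockout and GSI fold changes had no positive relation across genes. Over 12283 genes tested in both, Pearson's r was -0.04 and Spearman's rho -0.09, and 964 of 2056 knockout calls (46.9%) had the same sign under GSI. No gene was called under GSI, so most of its differences may be spread between libraries. A correlation near 0 therefore cannot show that the deletion differs from loss of Notch signalling. Nrarp was opposite in sign, 1.94 in knockout and -0.53 under GSI. It was also higher in untreated DN2a than in DN2b cells, by 0.96 (SE 0.26), though not called there (limma adjusted p = 0.0507). Dtx1 was lower in knockout and under GSI, by -0.85 and -1.70, though not called over all genes in either.

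**Figure D3:**
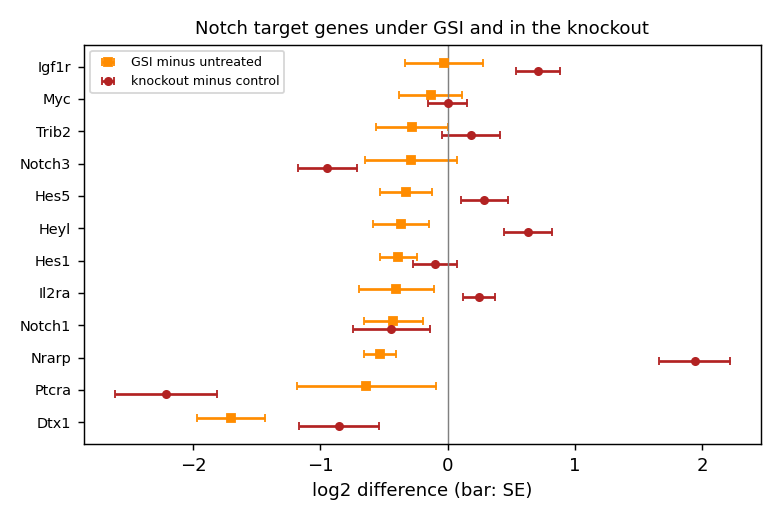
Log2 difference (x axis; bars, SE) of each Notch target gene tested in both comparisons, for GSI minus untreated (orange squares, n = 4 and 4) and knockout minus control (red circles, n = 14 and 11). Dtx1 is lowest under GSI at -1.70, and Nrarp lies at -0.53 under GSI and 1.94 in knockout.

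Untreated DN2a and DN2b cells were compared to describe the normal step across which Bcl11b rises. In DN2a cells 11 of 17 progenitor genes were higher and 6 of 20 T-cell receptor genes lower, and neither list passed as a set (adjusted p = 0.183 and 0.328). Spi1 was 49.3 ± 7.58 FPKM (SD, n = 4) in DN2a and 13.2 ± 5.08 FPKM (SD, n = 2) in DN2b, a log2 difference of 1.86 (SE 0.25, limma adjusted p = 0.0116). Cd3e was 5.78 ± 10.8 FPKM in DN2a and 114.1 ± 66.7 FPKM in DN2b, a log2 difference of -5.27 (SE 1.20, limma adjusted p = 0.0334). Of 13364 genes tested, 1799 were called, 565 higher and 1234 lower in DN2a; quantile normalization gave 692 and 580. Bcl11b differed by -3.39 (SE 1.03) and was not called (limma adjusted p = 0.0693).

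Progenitor regulators were higher in DN2a for 11 of 17 members (15 adjusted over the list alone) and lower for 0, led by Gfi1b (4.02), Nfe2 (2.81) and Mycn (2.49). T-cell receptor genes were lower for 6 of 20 (12 adjusted over the list alone), including Cd247 (-5.18) and Ptcra (-3.09). Notch target genes were lower for 4 of 13 (5 lower and 1 higher adjusted over the list alone): Ptcra, Dtx1 (-2.18), Notch1 (-1.95) and Notch3 (-1.81). The higher Notch target was Nrarp (0.96), as in knockout. Myeloid genes were higher for 4 of 13 (7 adjusted over the list alone), with Mpo (3.39), a granule enzyme gene, among them. Innate lymphoid genes were higher for 3 of 15, Tyrobp (5.61), Ccl5 (2.59) and Zbtb16 (2.54), while Id2 (-0.73) was not called. Among the remaining lists, T-lineage transcription factors had 1 of 17 lower, Tcf12 (-1.16), B-cell genes 1 of 5 higher, Btk (1.45), and gamma-delta genes 1 of 4 lower, Blk. Cytokine receptors had 1 of 13 higher, Il4ra (1.57), and 2 lower, Il17rb (-1.65) and Il9r (-1.43). Proliferation genes had 3 of 16 higher, Ccnb1 (1.15), Mcm3 (0.84) and Cdk1 (0.78), and 1 lower, Mki67 (-0.85). Erythroid markers had 2 of 3 higher, Hbb-b2 (4.71) and Hbb-b1 (1.94). Of 10 double-positive, 8 stromal and 10 immediate early genes 0 were called with limma. Adjusted over the list alone, these lists gave the same counts except for 1 lower B-cell gene, 3 lower cytokine receptors and 7 higher proliferation genes. Itga2b was higher by 5.89.

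With an estimated correlation none of the lists passed, the smallest adjusted p being 0.0858 for the myeloid list. It was 0.183 for progenitor, 0.324 for erythroid, 0.328 for T-cell receptor, 0.375 for proliferation, 0.389 for gamma-delta and 0.449 for Notch target genes. It was 0.571 for innate lymphoid, T-lineage factor and stromal genes, 0.82 for B-cell, double-positive and cytokine receptor genes and 0.887 for immediate early genes. The count rested on few libraries: it was 60 without DN2b replicate 1, which is titled DN3 but staged DN2b, 234 without DN2a replicate 4, the library of day 4.5, 802 without DN2b replicate 2 and 1184 without DN2a replicate 2. Titles of DN2a and DN2b share a month for replicate 1 and a date for replicate 2. On these 4 libraries 624 genes were called with title dates as a block and 68 without.

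The knockout differences resembled DN2a minus DN2b in part. Across 12467 genes Pearson's r was 0.41 and Spearman's rho 0.28, and 1613 of 2102 knockout calls (76.7%) had the same sign. Genes higher in both numbered 225 where 51 would be expected of independent lists (Fisher's exact test, p = 3.45e-94), and genes lower in both numbered 194 against 75.8 (Fisher's exact test, p = 2.62e-37). Genes called in opposite directions numbered 19 and 5, against 102.8 and 37.6. Genes are not independent of each other, so these p-values overstate the evidence. The overlap was smaller without DN2b replicate 1, the library titled DN3: 17 genes higher in both against 3 expected and 12 lower against 1.9, with r = 0.33. Without DN2a replicate 4 it was 57 against 8.7 and 34 against 9 (r = 0.39), and without DN2b replicate 2 91 genes were lower in both against 22.9. The innate lymphoid list had a median of 1.16 in knockout and 0.61 between stages, over 15 genes tested in both, while progenitor regulators had 0.78 and 1.60 over 14 genes.

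**Figure D4:**
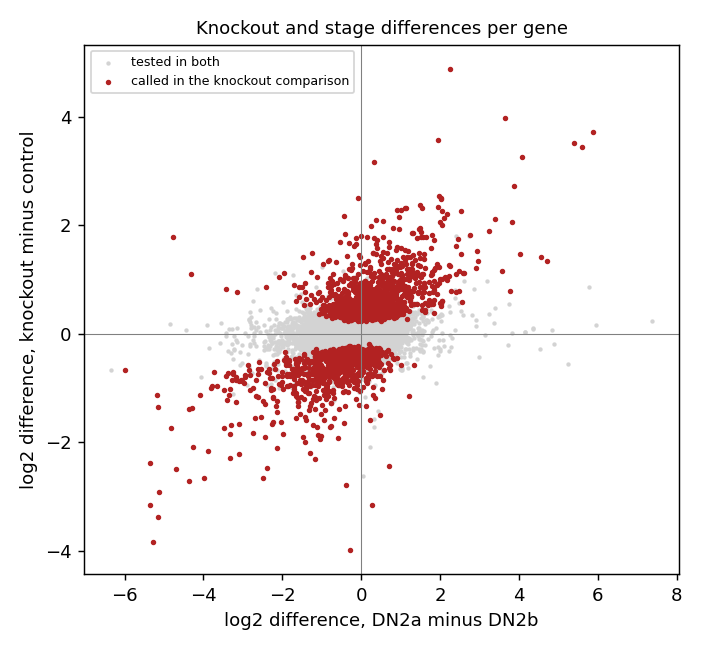
Log2 difference between knockout and control (y axis) against that between DN2a and DN2b (x axis) for the 12467 genes tested in both; red points were called in the knockout comparison. Red points lie mostly in the lower left and upper right, as 76.7% of them have the same sign.

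In libraries without replicates, no test can be made and the differences describe those libraries only. The 241 genes higher by 2-fold or more in fetal liver knockout had a median log2 difference of 1.57 between the LckCre thymic DN2 knockout and its DN3 control, and the 136 lower genes one of -1.36 (sort stage and genotype both differ). Cultured thymic DN3 cells in which deletion was induced with tamoxifen differed from the day 4 control by 1.46 and -0.83 for these lists, and from the day 3 control by 1.11 and -0.79. Knockout with empty vector differed from control with empty vector by 1.41 and -0.66. Both share title date, culture day and stroma with DL1 replicate 7 of their genotype, which helped choose the lists. This contrast may therefore not be independent of the lists. The control with empty vector stood apart, with 39.54% of its FPKM in 3 pseudogene entries against 1.07% in the knockout with empty vector. Lars2 was at 11100 FPKM against 482 and AY036118 at 3140 against 93.6. Rps27 was 12.7 FPKM in the knockout with empty vector, 382 in that control and 523 with the Bcl11b vector. All of these medians lay outside the 10000 matched random lists. Id2 was 98.6 FPKM in the thymic DN3 knockout, 12.4 in its day 4 control and 12.0 in the day 3 control; Nrarp was 35.4, 1.63 and 17. Cd3e stood at 140 FPKM in that knockout and in its day 4 control, while Ptcra was at the floor in the knockout and at 30.2 FPKM in that control. Cd160, an NK receptor gene, was 79.6 FPKM in that knockout and at the floor in the control. Other lists differed there as well: against the day 4 control 0 of 16 proliferation genes were higher (median -0.79), against 7 of 8 immediate early (1.57) and 4 of 4 erythroid genes (1.74). Against the day 3 control 4 of 16 proliferation (-0.47) and 6 of 8 immediate early genes (0.19) were higher. Progenitor genes were higher for 13 of 14 against day 4 (1.563) and 7 of 14 against day 3 (0.047). Myeloid genes were higher for 10 of 11 (0.631) and 3 of 11 (-0.74), so these lists depended on the control. Notch target genes were higher for 9 of 12 and 10 of 12. Hes1 was 62.7 FPKM in the thymic DN3 knockout, at the floor on day 4 and 14.7 on day 3. Dtx1 was 78, 10.1 and 22.4, and Spi1 4.18, the floor and 10.4. Neither Hes1 nor Dtx1 was higher in fetal liver knockout. In the LckCre contrast 0 of 8 immediate early genes were higher (-1.59).

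In 1 library of knockout cells given Bcl11b back for 36 h, both lists differed the other way from 1 library with empty vector. That empty vector library is the same as in the knockout contrast above. Any peculiarity of it would move these contrasts in opposite directions. Relative to the empty vector, 218 of the 241 higher genes were lower (22 were higher; median -0.48) and 116 of the 136 lower genes were higher (14 were lower; median 0.40), both medians outside the matched random lists. Zbtb16 went from 36.9 to 19.7 FPKM, Spi1 from 32.2 to 12.5 and Cd3e from 3.46 to 16.5. Ptcra went from the floor to 15.9 FPKM. T-cell receptor genes were higher for 18 of 19 members, while stromal markers were higher for 0 of 9 (median -0.90) and erythroid markers for 0 of 4 (-0.43). In bone marrow the higher list had a median of 0.24 in the library labelled knockout, with 184 of 241 genes higher and at percentile 100 of the random lists. The lower list had one of 0.03, at percentile 87.4. T-cell receptor genes were higher for 14 of 19 members (0.27) and progenitor genes for 4 of 14 (-0.31), unlike in the fetal liver. Myeloid genes were higher for 3 of 11 (-0.36), stromal markers for 2 of 9 (-0.92), erythroid markers for 0 of 4 (-0.29) and proliferation genes for 15 of 16 (0.18). Rag1 was 43.1 FPKM in that library and 1.25 in its control, and Gzma, a granule protease gene, 1210 and 137. Gzmb, another granule protease gene, went the other way, 2.68 FPKM in that library and 48.1 in its control.

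**Figure D5:**
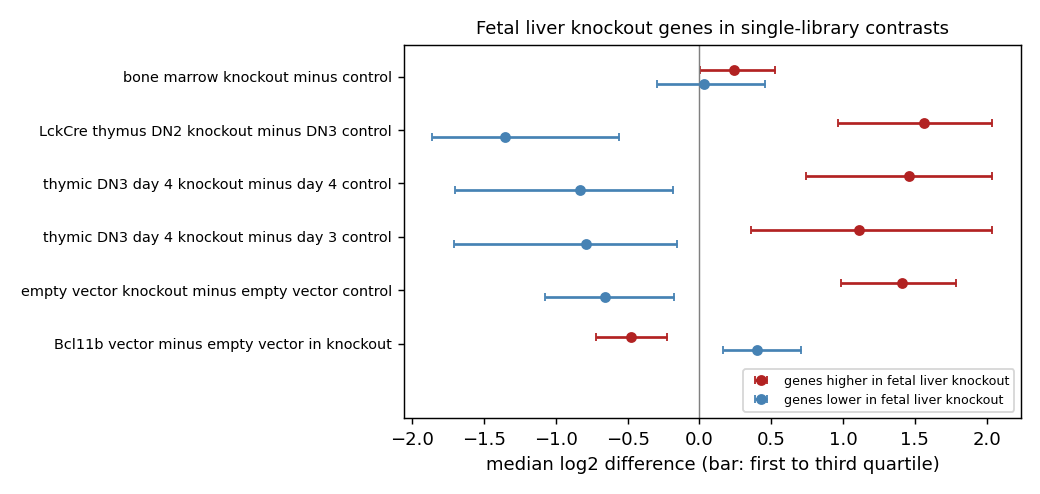
Median log2 difference (x axis; bars, quartiles over genes) of the 241 higher (red) and 136 lower (blue) fetal liver knockout genes in 6 contrasts of 1 library each. The medians are 1.57 and -1.36 in LckCre thymus, 0.24 and 0.03 in bone marrow, and change sides with the Bcl11b vector.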

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

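The random regroupings of the stroma, day and GSI comparisons, the division of knockout libraries by title and by stroma, the IL-7 and year interactions and the tests on the bone marrow library were chosen after the results were seen; the regrouping of the knockout comparison and the tests on sort phenotype and scaling were set before.

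Some libraries stood apart from their group by Dixon's test. Knockout DL1 replicate 8 had Gata3 at 135 FPKM, against 51.4 to 87.1 in the other 7 libraries, and Dtx1 at 43.8 FPKM, against 5.03 to 17.9. Knockout DL1 replicate 1 had Cd3e at 39.7 FPKM, where the other 7 reached at most 9.4. Knockout DL4 replicate 1 had Kit at 83.6 FPKM (others 38.6 to 55.1), and knockout DL4 replicate 2 had 5.76% of genes at the floor (others 2.05 to 3.31). Untreated DN2a replicate 1 had Cd3e at 21.9 FPKM, where the other 3 reached at most 0.997. The test was run on the fixed genes, total FPKM and the share of genes at the floor, not on every gene the report names. It gave 6 such values in 84 tests, and chance gives about 1 in 20.

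The fetal liver knockout difference differed with reduced IL-7 for 100 genes of 14271 tested (limma; 92 interactions positive and 8 negative, 4 knockout and 3 control libraries with reduced IL-7). The interaction was 4.08 for Zbtb16 (limma adjusted p = 8.02e-05), 1.67 for Id2 (0.0144) and 1.73 for Kit (0.0455). It was 4.42 for Dlk1 (0.00719), 4.56 for Trf (2.04e-07) and 2.02 for Maf (0.0282). An interaction with the earliest title year called 257 genes, 98 of them shared with the IL-7 one. The IL-7 count was 40 without knockout DL1 replicate 1, 49 without knockout DL4 replicate 1, 43 without control DL4 replicate 1 and 202 without knockout DL4 replicate 5. The year count was 162 without knockout DL1 replicate 1, 168 without knockout DL4 replicate 1 and 708 without knockout DL4 replicate 2.

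For this pattern, reduced IL-7 and the year cannot be told apart, because 0 control libraries with reduced IL-7 lay outside that year. In the following year, 1 pair of knockout libraries of the same date, DL4 replicates 5 and 4, differed in IL-7. Over the 92 genes higher in the interaction, reduced minus standard IL-7 had a median of 0.03 (quartiles -0.04 and 0.19). That pair cannot show a difference on the control side. Zbtb16 stood at 0.1, 0.4 and 1.5 FPKM in controls with reduced IL-7, against 8.8 to 21.1 FPKM in the other controls. In knockout libraries it was 42.5 to 83.1 FPKM with reduced IL-7 and 8.5 to 78 FPKM otherwise. Untreated DN2b cells of the earliest year, with standard IL-7, held 0.1 and 4.9 FPKM. Titles of the controls with reduced IL-7 name B6 without Cre, while those of the other controls name Cre. Whether the titles mark a difference in the cells was not tested. A single pair excludes nothing, so a growth factor effect, the year and the authors' batch adjustment each may be the cause.

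The similarity of knockout differences to DN2a minus DN2b may come from the sorting gates, as the protocol gives a DN2a phenotype for floxed cells, although only 8 of 14 knockout titles name it. For the 241 genes higher in knockout, knockout exceeded untreated DN2a by a median of 0.60 (quartiles 0.01 and 1.23; 0.541 to 0.648 with each DN2a library left out, 0.65 and 0.47 for knockout libraries titled DN2a and otherwise). These genes were chosen in the same libraries; chosen on DL1 and measured on DL4 the median was 0.52 (first quartile -0.08), and chosen on DL4 and measured on DL1 0.48 (0.10), so the gate is not excluded. For the 136 lower genes the median was 0.17 (quartiles -0.47 and 1.02; 0.06 without DN2a replicate 4), with 0.34 chosen on DL1 and measured on DL4 and -0.09 the other way, and a gate or a block at the DN2a stage stays open. Quantile normalization in both fits gave r = 0.43. A correlation across genes hardly changes when whole libraries are rescaled, and this step cannot undo an adjustment made gene by gene. The authors' scaling and batch adjustment therefore stay open. Culture time, the Cre virus and year also differed between the knockout and DN2a libraries and were not tested. All untreated DN2a libraries were grown on DL1 with standard IL-7. Knockout libraries measured on DL4 therefore also differed from them in stroma, and some in IL-7.

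In bone marrow, Bcl11b differed by 0 on the log2 scale between the library labelled knockout and its control, and knockout-higher genes had a median of 0.24, below the lowest of the other knockout contrasts (1.11). Other measures were mixed. Of the 241 knockout-higher genes 184 were higher. Id2 (46.3 against 30.7 FPKM), Zbtb16 (24.5 against 16.8) and Cd3e (33.8 against 50.8) went in the knockout direction. Among the fixed genes that went the other way were Ptcra (11.8 against 6.74) and Spi1 (5.05 against 13.6). A wrong label or cells without deletion may explain the unchanged Bcl11b and the low median. Reads from the part of the gene left after deletion stay open as the source of the Bcl11b signal, although the thymic knockout library, also made with CreERT2, differed by -1.7 from its day 4 control. The sex-linked genes Xist and Ddx3y also differed between the bone marrow libraries (below), and whether the cells differed in sex was not tested. No biological explanation was tested for the library labelled knockout.

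Random regroupings were counted for each comparison with at least 3 libraries per group. For the knockout comparison, 1 of 100 splits, the real one, gave as many as 2142 calls, and the highest other gave 0. The splits treated libraries of the same culture as separate, and the batch adjustment may have used genotype. They therefore do not exclude chance. For the stroma interaction 100 of 100 splits gave at least the real count of 0, the highest other giving 277, and for the day interaction 100 of 100, the highest giving 351. For GSI, 34 of 34 splits gave at least 0. With a real count of 0 every split gives as many, so these 3 counts say nothing about chance. Splits with high counts may reflect structure among the libraries other than the groups tested; what the stroma and day splits follow was not examined. The GSI split with most calls, 812, parted 0 pairs and set replicate 1 of both stages, titled with earlier months, against replicate 2; with pairs as a block GSI called 0 genes (limma, 1323 with an unadjusted p under 0.05). The 7 other splits that part all 4 pairs gave at most 1 call, and 1 split that follows stage could not be fitted.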

How the results depend on the processing

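The fits without the libraries of the earliest title year and without the libraries with Gm12563 at the floor, the 7 culture pairs, the stage fits with title dates and both added interactions were chosen after seeing the data. The knockout comparison stayed within 1.5 times of its 2142 calls under a pseudocount of 0.1, no filter, quantile normalization, robust variances, other covariates and averaged cultures, and 1830 to 2246 with each library left out.

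It called 1282 genes with date pairs as a replicate block, 858 with pairs of the same cultures averaged, 1396 with standard IL-7, 131 in pairs with controls titled DN2 (1 control and 1 knockout culture on 3 days), 988 on DL1, 451 on DL4, 475 in the earliest year, 270 in the middle year, 778 in the latest year and 1405 without the earliest year. All of these hold fewer libraries. Of the values for named genes, 2393 kept direction and side of the threshold, 217 kept direction and lost the call, 6 gained one and 5 reversed: Maf (-0.185) with controls labelled DN2, and Maf (-0.065), Irf8 (-0.182), Hbb-b2 (-0.197) and Fn1 (2.083, limma adjusted p = 0.013) in the middle year. The cause was not tested.

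DN2a against DN2b called 1065 genes with a pseudocount of 0.1, 234 without the day 4.5 library and 4891 with GSI libraries added, which pair with untreated ones and are not independent. With title dates as a block it called 624 on 2 pairs and 5359 with GSI libraries; leaving out each library gave 60 to 1406. Stroma calls ranged from 0 to 4, day calls from 0 to 2, and GSI and GSI by stage calls were 0 throughout with limma (297 and 129 with an unadjusted p under 0.05). A library alone in its group is assumed to vary like the others. The IL-7 interaction called 59 genes with quantile normalization and 40 to 202 with each library left out; the year interaction called 162 to 708.

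With the preset correlation the knockout lists had adjusted p = 3.61e-09 (innate lymphoid), 1.71e-09 (T-cell receptor) and 3.5e-08 (progenitor), and GSI 4.89e-07 (Notch) and 0.00868 (stromal). Stage lists had 0.00836 (innate lymphoid), 3.58e-05 (T-cell receptor), 2.73e-11 (progenitor), 4.09e-06 (myeloid), 0.000175 (proliferation) and 0.00912 (erythroid). Ignoring correlation between genes makes these smaller. The blocks changed the knockout T-cell receptor list to adjusted p = 0.0424 (0.0798 with pairs of the same cultures averaged) and gave r = -0.008 between knockout and GSI.

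In single libraries, a pseudocount of 0.1 and the use of all called genes gave medians for higher genes of 1.962 and 0.611 (LckCre), 1.861 and 0.739 (DN3, day 4), 1.473 and 0.837 (day 3), 1.585 and 0.675 (empty vector) and -0.544 and -0.213 (Bcl11b vector). For lower genes LckCre gave -1.565 and -0.51. All called genes gave 0.094 for bone marrow higher genes, and for lower genes -0.417 (day 4), -0.32 (day 3), -0.118 (empty vector) and 0.203 (Bcl11b vector). Depth is unknown from FPKM, so its limit on low values could not be assessed.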

Other observations

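Uncultured thymic DN3 cells, which belong to no comparison, had Bcl11b at 133.5 and 100 FPKM and Id2 at 6.7 and 5.9 FPKM. Between the bone marrow libraries, Xist was 36.3 FPKM in the library labelled knockout and 298 in its control, and Ddx3y 18.1 and 1.04. The pseudogene entries Gm12563, Gm15662 and Gm12913 took 0.76% to 39.54% of the FPKM of a library (median 5.87%). Gm12563 stood at the floor in 5 knockout and 3 control libraries of the fetal liver comparison and at 268464.6 FPKM in the control with empty vector. Without the libraries at that floor the knockout comparison called 1692 genes, 1169 higher and 523 lower against 1242 and 900 with all libraries, in a fit added after the data were seen.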
